A study of Homo sapiens with 18 samples.

How the data were processed

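The series holds 18 human chromatin immunoprecipitation sequencing (ChIP-seq) samples, of which 11 came with a list of peaks and 7 were input DNA without a list. The lists covered H3K27ac in 5 samples, H3K4me1 in 2 and RNA polymerase II (Pol II) in 4. The samples were grouped by the titles and source names that the submitters gave. Kelly and SH-SY5Y each contributed an H3K27ac, an H3K4me1 and a Pol II library from cells treated with DMSO, and a Pol II library from cells treated with THZ1. Per the labels' protocols, cells received 100 nM THZ1 or DMSO for 3 h. The remaining H3K27ac lists came from 2 high-MYCN and 1 low-MYCN patient samples, which are named here only by that group and a number. Their titles name no treatment, so it is unknown whether these cells received DMSO, as the lines did, THZ1 or neither.

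The submitters' processing notes name Bowtie, MACS 1.4.2, bedtools and the hg19 genome build, without saying which step each tool served. The caller's settings and the input library used for each list are not given in the sources used here. The deposited Pol II and H3K4me1 lists give each peak's position and, in an unnamed column, a number taken here as the authors' MACS score, which in that program is −10 log10 of the p-value. The lowest value in these lists was 50, which would stand for a p of 1e-05, the default limit of that program. The deposited H3K27ac lists give positions and names but no score, and most of their names join several peak calls, so each H3K27ac entry is a region merged from calls of the authors. Of these regions, 78.4% to 83.3% joined 3 or more calls, depending on the library. Each list belongs to a single sample, and whether any library was pooled before calling is not given in the sources used here. The score is the authors' own value for a peak, and it was used to rank, match or filter peaks within a list. Medians of the score describe each list, and since the score grows with depth they do not measure a change between lists.

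The number of reads behind each list is not given in the sources used here, so sequencing depth is unknown, and a longer list can come from a deeper library as well as from more binding. The number of autosomal regions ranged from 2160 to 103715. Percentages are printed with Wilson 95% intervals, which cover counting error only and say nothing about the spread between cultures or donors. The cell line comparisons have 1 library per arm, so they have no test and no p-value. The 2 high-MYCN patient samples are given one by one and as mean ± SD, and were set against the low-MYCN sample by an exact permutation test. The labels do not say whether these 2 samples came from separate donors, so their spread may be technical.

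Only the 22 autosomes were used, in every step. Overlap meant at least 1 bp. The overlap expected by chance was obtained by moving all regions of a chromosome by a random distance, 100 times. H3K27ac regions at most 12500 bp apart were stitched into domains, which were ranked by the base pairs that H3K27ac regions covered, and the 500 largest of each line were kept as a stand-in for super-enhancers, whose usual definition needs reads. The comparison level for shared largest domains came from 1000 random draws of 500 stitched domains, not matched on size. H3K27ac regions were called near Pol II within 2000 bp of a DMSO Pol II peak of the same line, and away from Pol II otherwise.

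For the effect of THZ1, the DMSO and THZ1 Pol II peaks of a line were joined when at most 1000 bp apart. A joined Pol II region was called lost with a DMSO peak only, kept with both, and gained with a THZ1 peak only. It counted as inside H3K27ac when it overlapped an H3K27ac region of the same line by at least 1 bp, and as outside otherwise. A peak outside H3K27ac that was joined to Pol II at H3K27ac thus counted in a region inside. Since THZ1 peaks took part in the joining, this can turn an outside DMSO peak into a kept region inside. It can thereby raise the percent lost outside and lower the percent lost inside. These words describe peak calls, not a measured amount of Pol II. Because peaks of low score are lost more often, the loss in the largest domains was set against 10000 random lists of the same size, drawn from the Pol II regions inside H3K27ac and matched in 10 bins of DMSO score. The loss outside H3K27ac was set against 10000 lists drawn with the same matching from regions inside. The central 95% of such lists describes these libraries and is not a test of the treatment.

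No hg19 gene annotation was used here. No gene or transcription start site was therefore placed on the peaks, and the planned comparisons by start site, the planned gene lists and the planned cell type marker lists were not used here. As the plan allowed for this case, regions replaced genes. Regions are printed with hg19 coordinates counted from 1 and with their chromosome band, from the hg19 band table in the R package circlize 0.4.16. Whether a region lies in an exon, an intron or between genes is not analysed here. The named regions followed a rule set in advance. It takes the 10 largest domains of each line and the 10 largest without H3K27ac of the other line. For Pol II it takes the 10 lost regions with the highest DMSO score, the 10 gained regions with the highest THZ1 score and the 5 kept regions with the highest DMSO score, and the text prints the leading ones. The other regions that the rule takes are not reported here. Runs of Pol II peaks and the chromosome arms were chosen after the data were examined.

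Alternatives fixed before the data were examined were a minimum score of 100, lists cut to equal length by score, an overlap of at least 50% of a region, stitching at 5000 bp, the 250 largest domains, unmatched random lists, a distance of 5000 bp from Pol II, and leaving out each high-MYCN patient sample. Added after the data were examined were H3K27ac regions joining 3 or more calls, lists cut to equal length by width, Pol II peaks joined within 2500 bp, leaving out 5 Mb around centromeres, leaving out band 2p24, the strongest Pol II region of each domain, matching on H3K4me1 as well, and, for the loss in the largest domains, Pol II lists cut to equal length by score. Also added then was a comparison of shared with Kelly-only regions of the same widths in the patient samples, from 10000 lists matched in 10 bins of width. Computations used Python 3.11.15, NumPy 2.4.6 and SciPy 1.17.1, and figures matplotlib 3.10.9. The matching was tested on simulated losses at the 3992 Kelly DMSO Pol II regions inside H3K27ac that the domain comparison draws on. In 4 of 100 simulations without an effect the list fell outside its central 95%, and with 15 points of added loss it lay above in 100 of 100. Losses were drawn independently per region from the same score bins, so this checks the computation and not the effect of regions clustering in domains. The sorting into lost and kept returned the simulated share in 3 of 3 simulations, each made from 6233 regions joined from the Kelly DMSO peaks alone. Whole joined regions were removed there, so this too checks the computation only.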

Results

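Neuroblastoma is a childhood tumour of the sympathetic nervous system, and extra copies of the transcription factor gene MYCN mark an aggressive form. The study profiled Kelly, an established neuroblastoma line with high MYCN, SH-SY5Y, an established line with low MYCN, and 3 patient samples. H3K27ac, a histone mark of active promoters and enhancers, was mapped in all 5 of them. H3K4me1, a mark of enhancers, and Pol II were mapped in the lines. Pol II was mapped again after 3 h with 100 nM THZ1, a covalent inhibitor of CDK7, a kinase that phosphorylates Pol II at the start of transcription. DMSO, the solvent, was the control. The series title names the question, which is how CDK7 inhibition affects transcription tied to super-enhancers in cells driven by MYCN.

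The Kelly H3K27ac list held 34134 autosomal regions covering 51.1 Mb, with a median width of 1152 bp. The SH-SY5Y list held 56317 regions covering 75.1 Mb, with a median width of 916 bp. H3K4me1 gave 54947 peaks in Kelly and 103715 in SH-SY5Y. Pol II gave far fewer, with 8199 peaks under DMSO and 7900 under THZ1 in Kelly, and 3066 and 2160 in SH-SY5Y. The patient lists held 7669 and 18306 regions in the high-MYCN samples and 38231 in the low-MYCN sample, with narrow median widths of 271, 292 and 454 bp. Each line had 1 library per mark and treatment, so no difference below has a replicate check.

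The largest H3K27ac domain of Kelly lay in band 3q21.3 (chromosome 3, 128025627 to 128217379), where H3K27ac regions covered 134 kb in Kelly and 42.6 kb in SH-SY5Y. It was followed by 15q24.1 (chromosome 15, 74419458 to 74615251) with 131 kb and 11q13.4 (chromosome 11, 72002932 to 72146248) with 92.6 kb. A domain in 2p24.3 (chromosome 2, 16049788 to 16136375) held 74.97 kb of H3K27ac in Kelly against 13.7 kb in SH-SY5Y. One in 2p23.2 (chromosome 2, 29419492 to 29541592) held 79.8 kb against 21.1 kb, and one in 9q34.2 (chromosome 9, 136374112 to 136582408) 87.0 kb against 29.8 kb. As background, 2p24.3 is the band of MYCN, 3q21.3 that of GATA2, 2p23.2 that of the receptor kinase gene ALK and 9q34.2 that of the noradrenaline synthesis gene DBH. These genes were picked after the bands were seen, each band holds other genes as well, and no domain was assigned to a gene here. Kelly cells carry extra copies of MYCN, and the copy number behind the 2p24.3 domain is not analysed here.

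In SH-SY5Y the largest domain lay in 17q22 (chromosome 17, 55582353 to 55704994) with 67.6 kb, of which Kelly regions covered 49.1 kb. The next lay in 6p22.2 (chromosome 6, 26155076 to 26254715), a band of the large histone gene cluster, with 67.0 kb against 36 kb in Kelly, and in 1q23.3 (chromosome 1, 163110352 to 163178566) with 62.3 kb against 42.7 kb. A domain in 15q24.1 was among the 10 largest of both lines, and all 10 largest of each line held H3K27ac of the other. Stitching at 5000 bp left 5 of the 10 in place in Kelly and 5 in SH-SY5Y. The largest Kelly domain without any SH-SY5Y region lay in 3p14.2 (chromosome 3, 62216732 to 62249015) and held 25.8 kb, and the next lay in 7q36.2 (chromosome 7, 154529147 to 154587599) with 23.4 kb. The largest SH-SY5Y domains without a Kelly region lay in 15q23 (chromosome 15, 71943737 to 72021847) with 38.6 kb and in 7q21.11 (chromosome 7, 80502076 to 80549486) with 33.1 kb.

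Across all regions, 64.3% of Kelly H3K27ac regions overlapped SH-SY5Y H3K27ac (95% interval 63.8 to 64.8, 21953 of 34134), against a mean of 5.11% when regions were moved at random. In the other direction, 41.4% of SH-SY5Y regions overlapped Kelly H3K27ac (41 to 41.8), against 3.29%. The Kelly list left 12181 regions found there only, and the SH-SY5Y list 33001. Shared regions were wider, with a median of 1439 bp in Kelly against 786 bp for those in Kelly only. With both lists cut to the same number of regions by width, the percentages were 54.0 and 52.2 and the SH-SY5Y-only count fell to 16312. Among the 500 largest domains of each line, 164 Kelly domains overlapped one of SH-SY5Y, where 1000 random draws gave a mean of 7.43 and at most 16. The draws came from stitched domains of all sizes. Large domains overlap more often by width alone, so these draws are not the chance level for large domains.

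By an overlap of 1 bp with any listed peak, H3K27ac away from Pol II carried H3K4me1 in most cases in both lines. It did so in 59.7% of 29280 Kelly regions (59.2 to 60.3) and in 66.1% of 53567 SH-SY5Y regions (65.7 to 66.5). With a score minimum of 100 the values were 41.0% and 47.9%, no longer most. Near Pol II the lines went opposite ways. In Kelly 40.1% of 4854 such regions overlapped H3K4me1 (38.8 to 41.5), less than away from Pol II, and in SH-SY5Y 75.6% of 2750 did (74 to 77.2), more than away from Pol II. When H3K4me1 had to cover at least 50% of a region, both lines were lower near Pol II, with 6.78% against 37.0% in Kelly and 18.4% against 36.6% in SH-SY5Y. Between the lines, 51.1% of Kelly H3K4me1 peaks overlapped SH-SY5Y H3K4me1, and 28.3% of SH-SY5Y peaks overlapped that of Kelly.

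In Kelly, Pol II peaks after THZ1 were concentrated at H3K27ac. Pol II peaks inside H3K27ac numbered 5015 under DMSO and 6942 under THZ1, whereas those outside went from 3184 to 958. The share inside was 61.2% under DMSO (60.1 to 62.2) and 87.9% under THZ1 (87.1 to 88.6). Covered length moved the same way, from 2032 to 2268 kb inside and from 702 to 212 kb outside. In SH-SY5Y both changes were in the opposite direction. Peaks inside H3K27ac went from 2551 to 1028 and peaks outside from 515 to 1132, so that the share inside fell from 83.2% (81.8 to 84.5) to 47.6% (45.5 to 49.7). Covered length went from 739 to 220.1 kb inside and from 108 to 270.1 kb outside. With the DMSO and THZ1 lists of a line cut to equal length by score, the share inside was 61.9% and then 87.9% in Kelly and 87.3% and then 47.6% in SH-SY5Y. The difference between the lines has no test, since each arm is a single library. A response to THZ1 can therefore not be told from a difference between the libraries themselves.

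**Figure D1:**
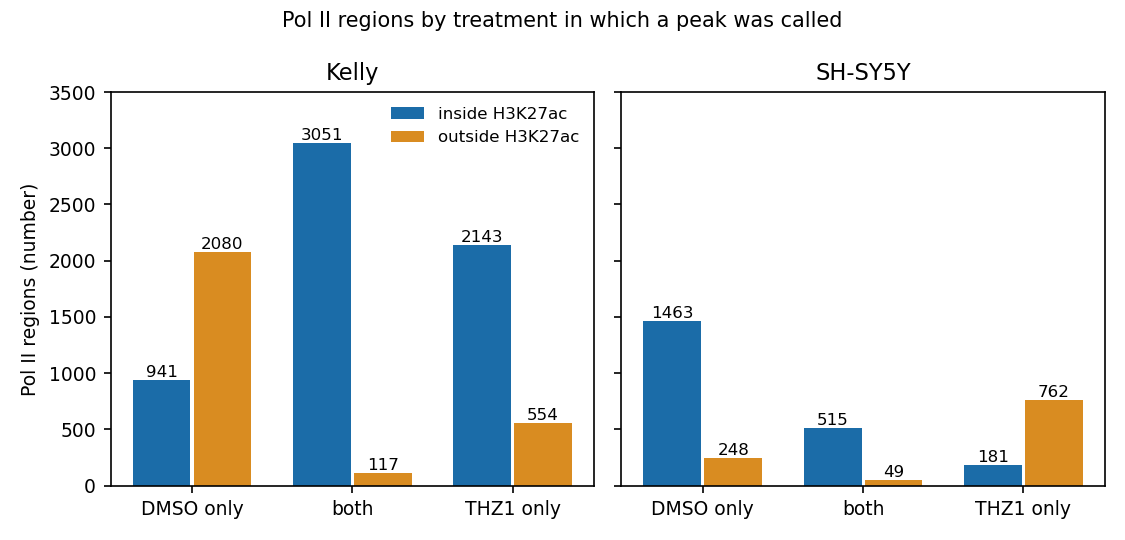
Number of Pol II regions (vertical axis) with a peak under DMSO only, under both treatments or under THZ1 only (horizontal axis), in Kelly (left) and SH-SY5Y (right), inside (blue) and outside (orange) H3K27ac of the same line, from 1 library per arm. In Kelly 2080 regions outside H3K27ac had a DMSO peak only and 117 had both, and in SH-SY5Y 762 regions outside had a THZ1 peak only.

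Joined into regions, the Kelly DMSO list split sharply by H3K27ac. Outside, 2080 of 2197 regions had no THZ1 peak, or 94.7% (93.7 to 95.5), and inside 941 of 3992, or 23.6% (22.3 to 24.9). A further 2143 regions inside and 554 outside appeared with THZ1 only. Regions inside with the same DMSO scores as those outside would have lost 38.6%, and the central 95% of 10000 such lists ran from 36.7% to 40.6%. In the highest of 10 score bins, 51.7% of 60 outside regions were lost against 1.5% of 400 inside. In SH-SY5Y the loss was broad, with 1463 of 1978 regions inside, or 74.0% (72.0 to 75.9), and 248 of 297 outside, or 83.5% (78.9 to 87.3). Kept regions inside H3K27ac had a median score of 247 in the DMSO list and 88.8 in the THZ1 list of SH-SY5Y, and of 112 and 154 in the lists of Kelly. In SH-SY5Y 75.8% of all THZ1 peaks scored under 100 against 65.5% of DMSO peaks, and in Kelly 55.8% against 66.7%. The score depends on depth, which is unknown. The SH-SY5Y loss outside lay within the range of score-matched inside lists, 82.5% to 89.2%. A THZ1 list that caught less would also give this, so the SH-SY5Y loss cannot be read as a response to THZ1 alone. Of 1509 Kelly DMSO regions that overlapped a SH-SY5Y DMSO region, 854 were kept in Kelly and lost in SH-SY5Y, 48 the reverse, 431 kept in both and 176 lost in both. Most of these counts depend on the score minimum. At 100 or more the regions gained outside numbered 50 in Kelly and 76 in SH-SY5Y, while those gained inside in Kelly numbered 1590. The minimum cut each list on its own, so a region whose DMSO peak scored under 100 could count there as gained. Of the 2143 Kelly regions gained inside without the minimum, 62.9% had a THZ1 score under 100.

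**Figure D2:**
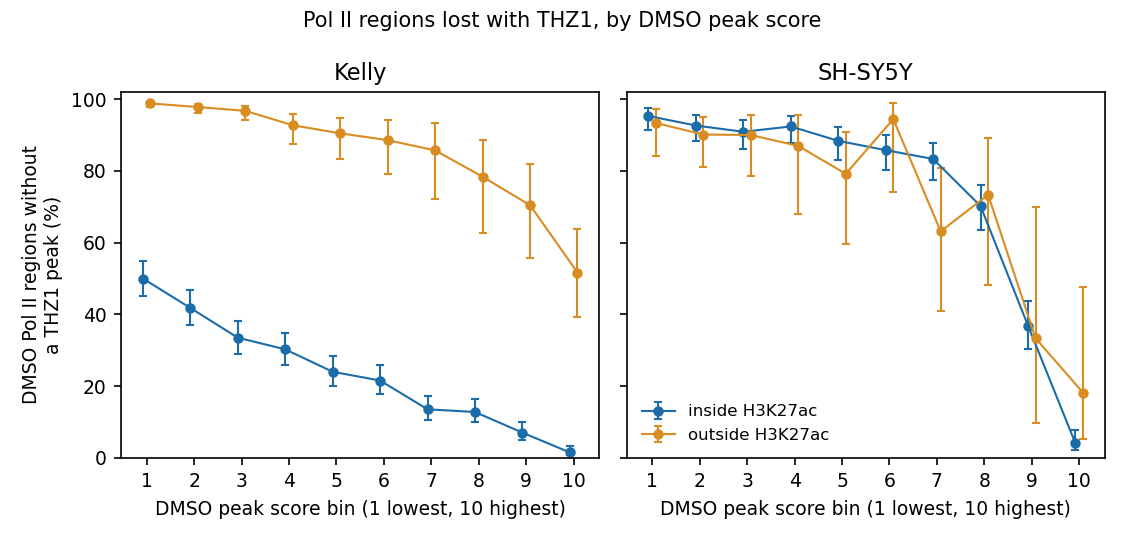
Percent of DMSO Pol II regions without a THZ1 peak (vertical axis) in 10 bins of DMSO peak score from low to high (horizontal axis), in Kelly (left) and SH-SY5Y (right), inside (blue) and outside (orange) H3K27ac, with Wilson 95% intervals as bars. In Kelly the outside points run from 98.8% to 51.7% and lie above the inside points, 50% to 1.5%, in every bin, while in SH-SY5Y the intervals overlap in every bin.

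The strongest Kelly Pol II region lost with THZ1 lay in 2p24.2 (chromosome 2, 16717109 to 16729042) with a DMSO score of 2346, outside H3K27ac. Another lay outside H3K27ac in 2p24.3 (chromosome 2, 16534823 to 16540263) with a score of 1430. Copy number in 2p24 is not analysed here. Between them in rank was a region in 1q23.3 (chromosome 1, 163106091 to 163115116), inside H3K27ac, with 9 DMSO peaks and a highest score of 2144. Of the 10 strongest lost regions in Kelly, 8 were outside H3K27ac, and 7 had no THZ1 peak within 2500 bp. In SH-SY5Y the strongest lost regions were in 19p13.3 (chromosome 19, 1269147 to 1269916, score 612) and 8q12.1 (chromosome 8, 56986667 to 56987231, score 494), and 2 of the 10 were outside. The strongest regions overall kept a peak. In Kelly these were led by 6p22.2 (chromosome 6, 26204343 to 26208025) and 1p36.22 (chromosome 1, 11967915 to 11970276), and in SH-SY5Y by 6p22.1 (chromosome 6, 27781234 to 27784184) and 17p13.1 (chromosome 17, 8076192 to 8077105). Many kept regions tied at the score of the fifth, 3100, and ties were named in genome order. All 55 kept Kelly regions and all 29 kept SH-SY5Y regions at or above that score were inside H3K27ac. This holds for joined regions and not for every peak in them. Among single Kelly DMSO peaks outside H3K27ac, one in 7p15.2 also scored 3100.

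Regions with a THZ1 peak only also differed between the lines. In Kelly the 10 strongest included 7 inside H3K27ac, such as 15q26.3 (chromosome 15, 101835211 to 101835652) and 3p21.31 (chromosome 3, 47822805 to 47823694), and were led by an outside region in 21p11.2 (chromosome 21, 9825434 to 9827586) within 5 Mb of the centromere. In SH-SY5Y all 10 were outside H3K27ac and 6 were within 5 Mb of a centromere, led by 6p11.1 (chromosome 6, 58776205 to 58780166), 7q11.21 (chromosome 7, 61967163 to 61973289) and 1p11.2 (chromosome 1, 121484035 to 121485436). Others lay in 16q11.2, such as chromosome 16, 46390918 to 46396884. Of 56 SH-SY5Y regions gained outside with a THZ1 score of 100 or more, 44 lay within 5 Mb of a centromere or in a heterochromatin band.

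Long runs of Pol II peaks outside H3K27ac were found in the Kelly DMSO list. Runs picked from the other lists are not reported here. Joining outside peaks within 5000 bp gave 99 runs of 5 or more, which held 787 DMSO peaks and 68 THZ1 peaks, and 72 of the runs held no THZ1 peak. Since runs were picked from the DMSO list, fewer THZ1 peaks in them are partly a matter of choice. The longest by count, in 13q31.3 (chromosome 13, 92004040 to 92016030), had 24 DMSO peaks covering 8939 bp and 3 THZ1 peaks covering 628 bp. In 1q44 (chromosome 1, 245000646 to 245017077) 23 DMSO peaks went to 3, and in 15q25.1 (chromosome 15, 78881042 to 78888375) 17 went to 0. A run in 7p15.2 (chromosome 7, 26220561 to 26236067) held 12 THZ1 peaks against 15 DMSO peaks.

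**Figure D3:**
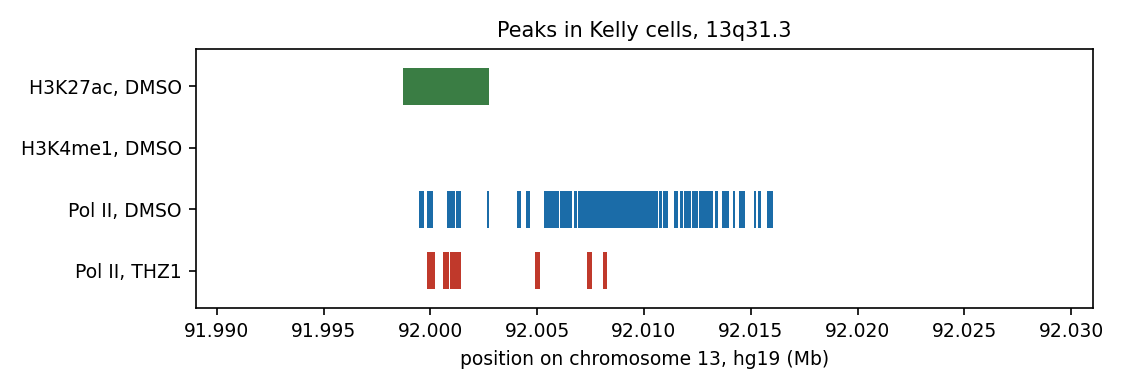
Peaks in Kelly cells along chromosome 13 in band 13q31.3 (horizontal axis, hg19 position in Mb), with a row each for H3K27ac, H3K4me1 and Pol II under DMSO and Pol II under THZ1, and each block 1 peak. The window held 1 H3K27ac region, no H3K4me1 peak, 29 Pol II peaks under DMSO and 7 under THZ1.

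Pol II loss in the largest H3K27ac domains, the comparison closest to the title of the series, was above the matched level in Kelly and below it in SH-SY5Y. In the 500 largest Kelly domains 138 of 369 Pol II regions were lost, or 37.4%, where score-matched lists of regions inside H3K27ac lost 20.6% (central 95% 17.1 to 24.1). The excess of 16.8 points lay at percentile 100 of 10000 lists. In the 500 largest SH-SY5Y domains 134 of 244 regions were lost, or 54.9%, where matched lists lost 62.3% (58.2 to 66.0). In both lines these regions are fewer than the domains, so many of the 500 held none and add nothing to the percentages. Taking only the strongest region of each domain left 190 regions in Kelly and 136 in SH-SY5Y. As a plain percentage the loss in the largest domains was higher in SH-SY5Y than in Kelly. With a score minimum of 100, and with only the strongest region of each domain, the SH-SY5Y value was within its range.

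Single domains varied. In Kelly, 5 of the 10 largest domains had fewer base pairs of Pol II peaks with THZ1. Pol II in the 3q21.3 domain went from 18875 bp of peaks under DMSO to 12875 bp under THZ1 while its peaks rose in number from 17 to 21, in 15q24.1 from 2024 to 154 bp, in 11q13.4 from 1242 to 0 bp and in 9q34.2 from 5626 to 840 bp. Of the 5 without a decrease, 1 in 16q24.1 (chromosome 16, 85478515 to 85661888) went from 0 to 495 bp. The remaining 4, with 2p24.3 and 2p23.2 among them, had no Pol II peak listed under either treatment. These 4 could therefore show no decrease, and a missing peak call does not mean that Pol II was absent. In SH-SY5Y the 6p22.2 domain went from 23750 bp to 13950 bp while its number of peaks rose from 20 to 54, and 1q23.3 went from 5595 to 2096 bp. In total 3 of the 10 largest SH-SY5Y domains had fewer base pairs of Pol II with THZ1, and several of the others had no Pol II peak under either treatment.

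The patient samples shared with the lines mainly what the lines shared with each other. In high-MYCN sample 1, 17.8% of the Kelly regions shared with SH-SY5Y overlapped a tumour region (17.3 to 18.3), against 2.003% of Kelly-only and 0.961% of SH-SY5Y-only regions. In high-MYCN sample 2 the values were 37.8%, 3.20% (2.90 to 3.53) and 3.57% (3.37 to 3.77). In the low-MYCN sample they were 60.2%, 17.6% (16.9 to 18.3) and 5.85% (5.60 to 6.11). With the line lists cut to equal length by width, and each patient list to its 7669 widest regions, the Kelly-only and SH-SY5Y-only values there were 5.95% and 1.66%. The high-MYCN means were then 2.12% and 1.80%, so the low-MYCN value for SH-SY5Y-only regions was no longer the higher one. Shared regions are wider, with a median of 1439 bp against 786 bp in Kelly. Kelly-only regions drawn with the widths of the shared ones gave 3.67%, 4.57% and 24.1% in these samples, still below the shared regions. Kelly-only regions were thus met 3.00 times as often as SH-SY5Y-only regions in the low-MYCN sample, 2.09 times as often in high-MYCN sample 1 and 0.898 times as often in high-MYCN sample 2. The high-MYCN mean was 2.603% ± 0.848 for Kelly-only and 2.26% ± 1.84 for SH-SY5Y-only regions (SD, n = 2), a difference smaller than the spread between the samples. By these percentages the line favoured was Kelly in the low-MYCN sample and in high-MYCN sample 1, and SH-SY5Y by a small margin in high-MYCN sample 2. The percentages divide by lists of unlike length, 12181 Kelly-only and 33001 SH-SY5Y-only regions. By count, high-MYCN sample 1 met 244 Kelly-only and 317 SH-SY5Y-only regions, high-MYCN sample 2 390 and 1177, and the low-MYCN sample 2139 and 1931. Over the 3 splits of the patient samples into 2 and 1, an exact permutation test (two-sided) of low against high MYCN cannot go below p = 0.333. It gave p = 0.333 for the Kelly-only percentage and p = 0.667 for the SH-SY5Y-only percentage and for the ratio, each 0.667 after Benjamini-Hochberg adjustment of these 3 exact tests.

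**Figure D4:**
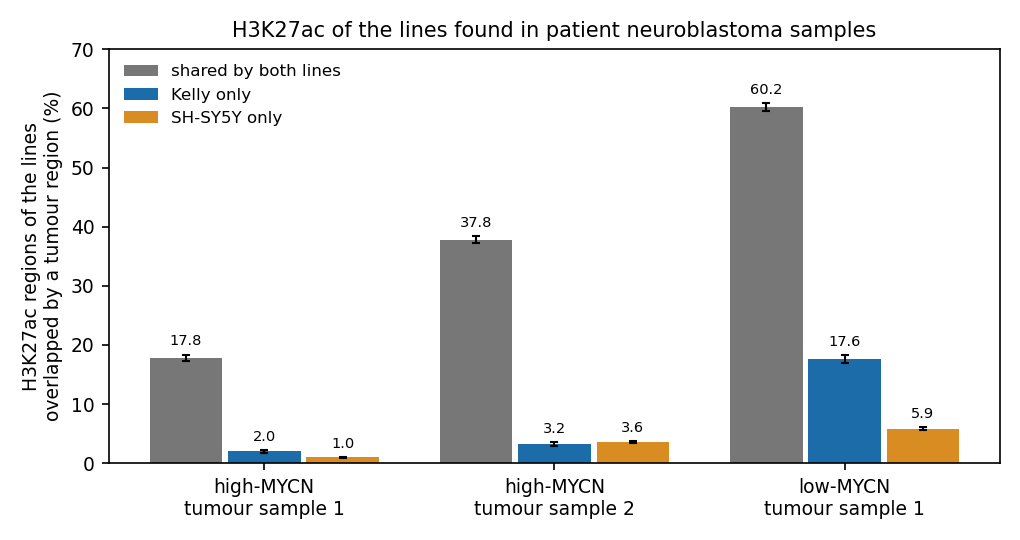
Percent of line H3K27ac regions overlapped by a tumour region (vertical axis) in each patient sample (horizontal axis), for Kelly regions shared with SH-SY5Y (grey), Kelly-only regions (blue) and SH-SY5Y-only regions (orange), with Wilson 95% intervals as bars. Shared regions reach 17.8%, 37.8% and 60.2%, and regions of a single line stay at 17.6% or below.

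Read from the tumour side, 81.4% of regions in high-MYCN sample 1 overlapped Kelly H3K27ac and 81.6% overlapped that of SH-SY5Y. In high-MYCN sample 2 the values were 75.3% and 82.6%, and in the low-MYCN sample 65.2% and 63.0%. In high-MYCN samples 1 and 2 and the low-MYCN sample, 52.2%, 58.6% and 84% of the 500 largest Kelly domains held a tumour region, and 40.2%, 58.6% and 69.2% of those of SH-SY5Y. Domains are far wider than single regions, so these percentages are not comparable with those for regions. Of the 10 largest Kelly domains 9 held a region of both high-MYCN samples, and of the 10 largest SH-SY5Y domains 6 did. The tumour lists differ in length, so percentages are best compared within a tumour.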

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

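Of the tests given here, the score-matched comparison of outside with inside regions, the use of the minimum score on DMSO scores alone, the strongest region of each domain, the matching on H3K4me1, the distance to centromeres and the added comparisons with the whole list, at equal scores, with lost regions or with heterochromatin bands were chosen after the results they bear on had been seen. The tests of the nearest inside region, of scores under 100 and of regulatory DNA were set before those results were seen, though after the lists had been examined. Changes that ran in opposite directions in Kelly and SH-SY5Y were picked out, and none of these differences was tested, since each arm is a single library. Pol II peaks inside H3K27ac rose by 38.4% in number with THZ1 in Kelly and fell by 59.7% in SH-SY5Y. Outside H3K27ac they fell by 69.9% in Kelly and rose by 119.8% in SH-SY5Y. By covered length the Kelly rise inside was smaller, from 2032 to 2268 kb, as the median peak width there went from 331 to 259 bp. Pol II loss in the 500 largest H3K27ac domains lay 16.8 points above score-matched lists in Kelly and at -7.377 points relative to such lists in SH-SY5Y.

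In Kelly, 94.7% of Pol II regions outside H3K27ac had no THZ1 peak. A THZ1 list that caught less by score alone would lose inside and outside regions of the same score alike. Score-matched inside lists lost 36.7% to 40.6%, which argues against that in Kelly. Joining DMSO peaks to THZ1 peaks at H3K27ac can widen this gap, and by how much was not measured. The lists were not matched on width, and lost regions had a median width of 132 bp outside against 260 bp inside. Lower sensitivity to narrow peaks therefore stays open. In SH-SY5Y the loss outside, 83.5%, lay within its matched lists, 82.5% to 89.2%, so a list that caught less stays open there. Weak DMSO calls do not account for the Kelly difference among regions of higher score. Of outside regions with a score of 100 or more, 181 of 244, or 74.2%, were lost (68.3 to 79.3). Inside, 215 of 1942 were lost, or 11.1% (9.75 to 12.5). These 181 are a small part of the 2080 lost outside regions, whose median DMSO score was 58.6. For those under 100 weak calls stay open. Whether THZ1 removed Pol II beyond H3K27ac more than at the H3K27ac next to it may not be read from the test set for it, whose bound of 50% lay under the 76.4% of all inside regions that were kept. The nearest inside region within 50 kb was kept for 88.1% of 952 lost outside regions, and the 649 different nearest regions, counted once each, were kept in 87.5% (84.8 to 89.8) against 81.5% at the same scores, which leaves the hypothesis open.

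In the largest Kelly domains 37.4% of Pol II regions were lost. Counting several regions of a domain as if independent is argued against by the strongest region of each domain alone, with 28.4% lost against 11.1% to 20% in matched lists. A larger share of H3K4me1 does not account for all of it, since lists matched on H3K4me1 as well lost 20.6% to 27.4% against the same 37.4%. The excess was 13.55 points with this matching and 16.8 points without it. A stronger effect of THZ1 in these domains may be considered as a hypothesis for Kelly. The lists were not matched on the width of Pol II regions or their place in a domain, so these remain open as well. The Kelly excess has no replicate, and in SH-SY5Y the loss, 54.9%, lay below its matched lists.

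In SH-SY5Y 762 Pol II regions outside H3K27ac appeared with THZ1. Pol II at DNA that the other lists mark as regulatory is argued against for most of them, since 8.53% (6.75 to 10.7) overlapped H3K4me1 in SH-SY5Y or H3K27ac or Pol II in Kelly, against 35.5% (29.8 to 41.6) of SH-SY5Y regions lost outside H3K27ac, and 4.33% by chance; regulatory DNA in none of these lists stays open. Weak calls near the caller's threshold may account for most, since 92.65% scored under 100, although the whole THZ1 list had 75.8% there and the bound set was 50%. Repeat sequence near centromeres is not the cause of most of them, with 24.8% within 5 Mb of a centromere, but 44 of the 56 with a score of 100 or more lay there or in a heterochromatin band, so the weak and the strong part may differ in source. No biological explanation was tested for the strong part.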

How the results depend on the processing

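The settings of 3 or more joined calls, equal length by width, joining within 2500 bp, centromeres, band 2p24, the strongest region of each domain H3K4me1 matching and, for the loss in the largest domains, equal length by score were chosen after the data were examined. The Kelly excess of Pol II loss in the largest domains stayed above matched lists under all its alternatives, from 13.2 to 23.4 points. The SH-SY5Y value stayed negative under all of its own, but lay within matched lists at a score of 100 or more (-2.941 points) and with the strongest region only (-3.676 points). It was -10.4 points with the 250 largest domains and -19.26 points with unmatched lists. Joining Pol II peaks within 2500 bp and leaving out 5 Mb around centromeres moved none of 18 results each beyond its limit. Leaving out a high-MYCN sample leaves the value of the other, 2.003% or 3.20% for Kelly-only and 0.961% or 3.57% for SH-SY5Y-only regions, and without sample 1 the order of these turns. Leaving out band 2p24 removed no Kelly region of the largest domains and so tests nothing there.

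A score minimum of 100 left, in Kelly, 600 lost, 1358 kept and 1590 gained regions inside and 229 lost, 34 kept and 50 gained outside, with 30.6% lost inside and 87.1% outside. In SH-SY5Y it left 572 lost, 225 kept and 9 gained inside and 52 lost, 6 kept and 76 gained outside, with 71.8% and 89.7% lost. Fewer peaks enter by construction. H3K4me1 at H3K27ac then stood at 41.0% away from and 22.3% near Pol II in Kelly, and 47.9% and 57.5% in SH-SY5Y. Equal length by score gave 68.0% lost inside and 74.5% outside in SH-SY5Y, with 108 lost outside, and H3K4me1 at 50.2% away and 61.0% near.

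With at least 50% of a region covered, the overlaps of the lines were 58.15% for Kelly and 37.1% for SH-SY5Y. H3K4me1 stood at 37.0% away and 6.78% near in Kelly and 36.6% and 18.4% in SH-SY5Y, which turns the order in SH-SY5Y. Of Kelly-only regions 0.517% were met in the high-MYCN samples and 9.90% in the low-MYCN sample, and of SH-SY5Y-only regions 0.483% and 3.02%. With 3 or more calls, Kelly-only regions numbered 8039, overlaps were 70% and 45.0%, H3K4me1 62.5% away in Kelly and 72.5% away and 77.7% near in SH-SY5Y, and the low-MYCN sample met 18.7% and 6.29%. With equal length by width, overlaps were 54.0% and 52.2%, SH-SY5Y-only regions 16312, and the low-MYCN values 5.95% and 1.66%. The high-MYCN means were 2.12% and 1.80% with patient lists cut likewise. Beyond 5000 bp as the limit, 42.2% of Kelly regions near Pol II had H3K4me1. With the 250 largest domains 78 were shared. For the moved values the cause was not tested, except where the setting itself leaves fewer regions.

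Not run were a score minimum, equal length by score and ranking by summed scores for H3K27ac, since these lists hold no score, and the settings by transcription start site. No paired analysis was possible because the groups with more than 1 numbered sample are inputs without a list and the high-MYCN tumours, which share fewer than 2 numbers with the group they are compared with. Unknown read depth limits each statement that a peak is lost or gained.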

Other observations

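The values in this part were chosen after the data were examined. The balance of H3K27ac between the lines differed by chromosome arm. Relative to all autosomes, Kelly had the highest ratio of covered length to SH-SY5Y on 22q (1.59), 20q (1.56) and 17q (1.46), and the lowest on 18q (0.400), 8p (0.560) and 2q (0.635). On 18q Kelly H3K27ac covered 373 kb and SH-SY5Y 1371 kb. Copy number of the lines is not analysed here.

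In band 2p24.3 the Kelly H3K27ac list held 45 regions covering 206 kb, and the SH-SY5Y list 105 regions covering 172 kb. H3K4me1 there covered 323 kb in Kelly and 127.5 kb in SH-SY5Y. Pol II in the band went from 18 to 7 peaks with THZ1 in Kelly, covering 21.5 and then 15.9 kb, and from 30 to 21 peaks in SH-SY5Y.

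Lost Kelly Pol II regions outside H3K27ac lay a median of 21.7 kb from the nearest H3K27ac region, and those of SH-SY5Y 5.51 kb. Of the Kelly H3K27ac regions, 2967 were also covered in SH-SY5Y and in all 3 patient samples.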
